A study of Streptomyces coelicolor with 7 samples.

How the data were processed

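Messenger RNA levels were followed over time in Streptomyces coelicolor M145-OA, described in the labels as an engineered strain, without an explanation of the letters OA. S. coelicolor is a filamentous soil bacterium that makes several antibiotics, and M145 is its usual laboratory strain, which lacks the plasmids of the wild type. Per the labels, the cells grew in shaken flasks of a supplemented minimal liquid medium at 28°C, were collected by fast filtration and were frozen in liquid nitrogen. Samples were taken 18, 24, 30, 36, 42, 48 and 60 h after the start of fermentation, and the series is described as covering exponential, transitional and stationary growth without a statement of which time belongs to which phase.

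Each of the 7 samples was hybridised to a NimbleGen array with 2 dyes. Per the labels, Cy3 carried the RNA of the sample and Cy5 carried a common reference, a separate RNA of 18 h called 18hA. The orientation was the same on all 7 arrays, so a dye effect that depends on the gene was not balanced by a swap. The first array compared an RNA of 18 h, called 18hB, with the reference, and served as the measure of error and of dye effect. There was 1 array per time. Nothing in the labels says that the samples came from separate cultures. The p-values of single genes below therefore rest on the distance of these 7 arrays from a fitted line or smooth curve. That distance holds scatter, which may be technical, and, for a gene that moves in a step, the misfit of the line or curve. P-values of gene lists rest on the spread over genes or on the order of the arrays. None of them measures variation between cultures.

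The deposited tables hold, per the file headers, a signal intensity for each channel and their linear ratio, with 1 value per gene. The steps from probes to gene values, the background correction and the scaling within an array are not given in the sources used here. Each table lists 7730 features, of which 7729 are protein-coding genes of the chromosome with a locus tag and coordinates, in the numbering of the annotation that the tables call build 1201. The other is a gfp feature, the gene of the green fluorescent protein. The direction was checked against the values: the deposited ratio equals the Cy3 intensity over the Cy5 intensity within a relative gap of 0.00017 at 18 h and 2.22e-16 at the later times. A single matrix of deposited ratios for the whole series equals the ratio of each array to within 5e-05.

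The deposited ratio was not made in the same way on all arrays. At 18 h all ratios were whole multiples of the last of 4 decimals. At 24 and 30 h all were 1.05 times such a number. At 36 to 60 h they were 1.05 times a number in steps of the last decimal divided by 2, as the mean of a pair of values would be, with between 49.6% and 50.2% falling on whole steps (relative tolerance 2e-07). The origin of the factor and of the averaging is not given in the sources used here. At 24 to 60 h the deposited Cy3 intensity is the Cy5 intensity multiplied by this ratio, so it is not an independent reading. These 3 classes of arrays follow each other in time, so class and time are partly confounded. The tables also give call letters (P or M for a channel, P or A for the ratio) whose meaning is not given in the sources used here. They were not used as a filter, and no lower bounds were set for dim genes. The median Cy5 intensity lay between 756 and 914 and its minimum between 142 and 203, so a gene that is nearly silent in the reference still has a signal there, and ratios of such genes are compressed.

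The deposited ratio was taken to log2 and used as it stands, with no further normalization. The design fixed before the data were examined foresaw normexp and loess for raw intensities and the deposited normalized values otherwise, and the second case applied. A linear trend was fitted to each of the 7729 genes over the 7 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, slope on hours, 5 residual degrees of freedom, prior degrees of freedom 2.51). The slope is given as the fitted log2 change over the 42 h from 18 to 60 h, with its standard error. Any smooth change over time, straight or curved, was tested with limma's F-test of a natural spline with 2 degrees of freedom, which does not test for departure from a line. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. All tests were two-sided. Genes at least 2-fold higher or lower (1 on the log2 scale) than on the 18 h array, or than on the array before, were counted without a test, since a time has 1 array. Subtracting the 18 h array removes a dye effect of the gene, but adds the error of that array to every later time.

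The analysis used 25 gene lists, fixed by locus tag before the data were examined. They cover antibiotic and other secondary metabolite clusters (actinorhodin, undecylprodigiosin, calcium-dependent antibiotic, coelimycin, grey spore pigment, siderophores, terpenes, ectoine), development (aerial hyphae surface proteins, gas vesicles, developmental regulators), growth (ribosomal proteins, transcription and translation factors, DNA replication, fatty acid synthesis), energy metabolism (respiratory chain, tricarboxylic acid cycle, glycolysis, nitrate reductases), responses to nutrients and stress (phosphate, nitrogen, heat shock, osmotic and oxidative stress), antibiotic regulators and sigma factors. Of their 373 loci, 370 were used. The array lacked 1 locus (SCO6271), and 2 were left out after the annotation in the tables was read, SCO1600 as an initiation factor among the ribosomal proteins and SCO1601 as a protein of unknown function among the translation factors. A list's trend against all other genes was tested with limma's camera at a preset correlation between genes of 0.01, with the correlation estimated from the data as an alternative. The list's mean log2 ratio was also set against time with Pearson's r and Spearman's rho, and exact two-sided permutation p-values over all 5040 orders of the arrays. The smallest p that Spearman's rho can give is 4e-04. With Pearson's r a smaller one is possible, since the times are unevenly spaced. The p-values of each test were adjusted over the 25 lists. At each time, a list's median was placed among 10000 random lists of the same size matched on mean signal in 10 bins.

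Genes are named by a rule fixed before the data were examined. It takes the 10 largest fitted rises and the 10 largest falls past the threshold, and the 3 highest and 3 lowest differences from 18 h at each later time. It also takes the 5 genes with the largest excess of the middle times over both ends among those past the spline test, the highest and lowest member of each list, and every member of the lists of antibiotic regulators, developmental regulators and sigma factors. Any other gene is said to have been chosen after its values were seen. Gene symbols are those written in the tables. The reference table of gene names supplied with the series matched 0 of the locus tags, so a gene without a symbol is given by its locus tag and the function in the tables. Of the features, 3415 are called hypothetical proteins, and 29 stand for more than 1 near-identical locus.

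The fits were tested on simulated data for the 7729 genes, with noise like that around the fitted lines and 50 genes changed at each size. For the linear trend, 14%, 40%, 76% and 90% of genes changed 2-, 4-, 8- and 16-fold over the course were recovered, and 8 of the 118 genes called were unchanged. The camera step called 5 of 5 shifted lists and 0 of 15 unshifted ones. Noise was drawn independently for each gene, so false calls for lists whose genes move together were not tested. In the real lists the estimated correlation between genes ranged from -0.019 (DNA replication) to 0.979 (ectoine). The spline test called 74 genes, of which 1 was unchanged. All simulated changes were straight in time, so recovery of curved or stepped courses was not tested. Precision is limited by the number of arrays.

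The alternatives tried for the trend, counts and lists were median centring of each array, the matrix of the series, the Cy3 intensity alone after quantile normalization, leaving out the dimmest 25% of genes, leaving out each array in turn, an intensity trend with a robust prior, log2 of hours, a fold minimum, thresholds of 1.5- and 4-fold, the ratio without subtraction of the 18 h array, the list median, and an estimated correlation. Others were added after the data were seen: division of the later ratios by 1.05, loess within the array, the class of ratio as a batch term, the 36 to 60 h arrays alone, and the 24 and 30 h arrays averaged into 1. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.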

Results

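Gene expression of the engineered Streptomyces coelicolor strain M145-OA was measured at 7 times of a liquid culture, from 18 to 60 h, with 1 array per time and a common reference RNA of 18 h on every array. The question, per the labels, was how the transcriptome differs between growth phases. Values are log2 ratios of a sample to this reference for 7729 chromosomal genes. All genes named lie on the S. coelicolor chromosome, and each feature is a protein-coding sequence without introns, given with the coordinates in the tables (build 1201). The median intensity per array was between 900 and 965 in the sample channel and between 756 and 914 in the reference channel. There were no replicates at any time, so an error is given for fits over the course and as an SD over the genes of a list.

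The 18 h array set 2 RNAs of the same time against each other and shows how far single genes move without a difference in time. On it 67 genes were at least 2-fold higher and 222 at least 2-fold lower in 18hB than in 18hA, together 3.7% of genes, and the SD of the log2 ratio over genes was 0.47. Single genes lay much further out. SCO1202 (1273700 to 1275238), an ATP-dependent DNA ligase, stood at 5.20 on this array, SCO5656 (6155449 to 6155949), a transcriptional regulator, at 3.31 and its neighbour SCO5655 at 2.87. These 3 genes are among the lowest at later times below because of their value at 18 h. Features of the plasmids that M145 lacks, or random control probes, were not among the features of the tables, so no floor of the signal was measured. The reference channel, which held the same RNA on all arrays, had correlations across genes between arrays of 0.969 to 0.985, and SDs of the log2 differences between 0.28 and 0.39.

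Already at 24 h, the antibiotic clusters of the strain stood far above 18 h. The genes for coelimycin, a yellow polyketide, were on average 43.3-fold higher (mean log2 difference 5.44, SD 0.92 over 19 genes, all 19 at least 2-fold higher). Those for actinorhodin, the blue polyketide antibiotic, were 11.8-fold higher (21 of 22 genes), those for the calcium-dependent lipopeptide antibiotic 6.36-fold (34 of 40) and those for the red pigment undecylprodigiosin 4.27-fold (20 of 22). Genes of fatty acid synthesis were 5.45-fold higher (6 of 7), genes of nitrogen assimilation 5.78-fold (8 of 10) and heat shock genes 3.47-fold (5 of 8). All 4 genes for ectoine, an osmoprotectant, were at least 2-fold lower at every later time, with a mean of 0.185 of the 18 h level at 24 h. For the fatty acid, heat shock and ectoine lists, part of the difference lay between the RNAs of 18 h. Their mean log2 ratios of 18hB to 18hA were -1.27, -0.64 and 0.66. Against the 18hA reference, their means at 24 h were 1.18, 1.15 and -1.77. At 24 h no random list of equal size and matched signal had a median as high as those of the coelimycin, actinorhodin, calcium-dependent antibiotic, undecylprodigiosin, nitrogen, fatty acid, aerial hyphae and nitrate reductase lists (percentile 100), and none had one as low as the ectoine and ribosomal protein lists (percentile 0).

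Over all genes, 1322 were at least 2-fold higher and 476 at least 2-fold lower at 24 h than on the 18 h array. At 30 h the counts were 1298 and 435, at 36 h 1457 and 620, at 42 h 1602 and 810, at 48 h 1486 and 572, and at 60 h 1340 and 506. Of all genes, 579 were higher and 148 lower at all 6 later times. The share of higher genes among those at least 2-fold from 18 h was 66.4% to 74.9% in the ratios, 63% to 71.4% after median centring and 60.8% to 69.3% after loess, an alternative chosen after the data were seen. With the sample channel alone, quantile normalized so that all arrays have the same distribution, it was 46.4% to 48.3%. At 24 to 60 h the deposited sample intensity is the reference intensity multiplied by the ratio, so this is not an independent check. The median of all genes at 60 h lay 0.125 above 18 h in the ratios and 0.011 above it after median centring. The sign of a list's median difference from 18 h turned with the sample channel alone in 12 of 150 cases. These were the respiratory chain list at all 6 later times, the DNA replication list at 24, 30 and 60 h, the stress list at 48 h, and the calcium-dependent antibiotic list at 42 h (0.63 in the ratios, -0.01 alone) and 48 h (0.10 and -0.43).

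The highest genes at 24 h lay in the coelimycin cluster. The diaminobutyrate-pyruvate aminotransferase gene SCO6279 (6936149 to 6937705) was 6.50 above 18 h on the log2 scale, the hypothetical protein gene SCO6283 6.29 and the regulator gene SCO6288 (6947584 to 6948414) 6.26. SCO6279 and SCO6283 were again highest at 30 h with the transporter SCO6278. At 36 h the highest were in the actinorhodin cluster, the transporter gene actII-2 (SCO5083, 5524073 to 5525809), the oxidoreductase gene SCO5075 and actII-3 (SCO5084). At 42, 48 and 60 h SCO5075 and actVB (SCO5092, 5534558 to 5535091), for a polyketide dimerase, were among the 3 highest. The difference for actVB was 7.77 at 60 h. They were joined by SCO4881 at 42 and 48 h and by SCO7683 at 60 h. The lowest at 24 h, apart from SCO1202, were SCO4498 (4916551 to 4917873), a proton transport protein, at -4.61, and the nitrite/sulfite reductase gene SCO6102 (6700888 to 6702585) at -4.45. At 60 h their differences from 18 h were 0.30 and 0.27. The 3 lowest included gluB (SCO5776) at 30 and 48 h and gluD (SCO5774) at 30, 42 and 48 h, both for glutamate uptake, with log2 ratios of -4.44 and -4.45 at 30 h. Others were the dehydrogenase gene SCO4945 (5378899 to 5379939) at 36, 42 and 48 h, with a log2 ratio of -4.22 at 42 h, and ahpD (SCO5031) at 42 h. None of these single differences has a replicate.

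**Figure D1:**
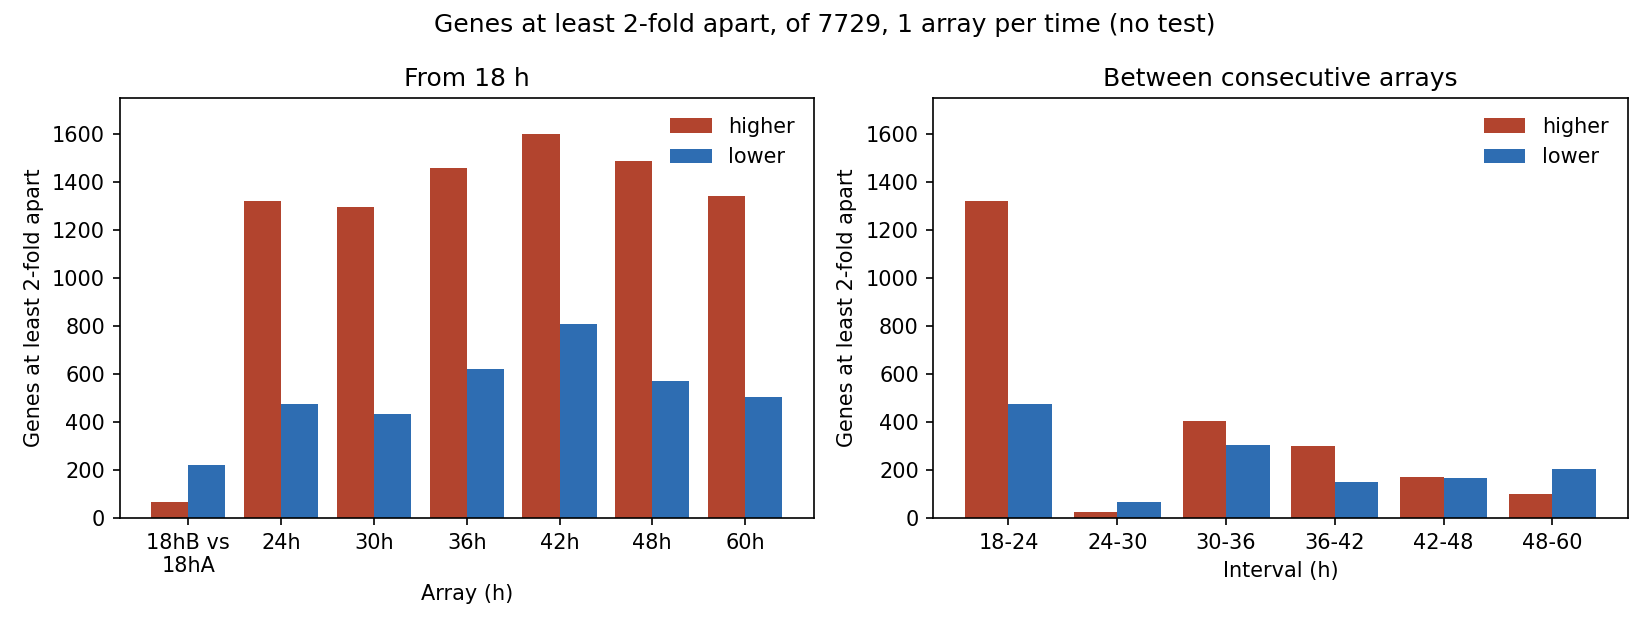
Bars count the genes, of 7729, at least 2-fold higher (red) or lower (blue) than on the 18 h array (left, with the 18 h self comparison) and than on the array before (right), 1 array per time. The interval from 18 to 24 h holds 1798 such genes and that from 24 to 30 h holds 95.

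Of the intervals between neighbouring arrays, that from 18 to 24 h held the most 2-fold steps and that from 24 to 30 h the fewest. Between 30 and 36 h the actinorhodin list moved up again, from 10.8-fold to 35.8-fold over 18 h, and the coelimycin list down, from 49.2-fold to 13.8-fold. Between 36 and 42 h the phosphate starvation list went from 1.08-fold to 12.2-fold, and the ribosomal protein list from 0.573 to 0.265 of its 18 h level, with 41 of its 45 genes then at least 2-fold lower. Genes at least 2-fold apart numbered 1798 from 18 to 24 h, 95 from 24 to 30 h, 709 from 30 to 36 h, 455 from 36 to 42 h, 340 from 42 to 48 h and 305 from 48 to 60 h. The intervals with the highest counts, 18 to 24 h and 30 to 36 h, are those where the class of ratio changes. In these intervals a difference between classes of arrays cannot be told apart from time. The reference channel, with the same RNA throughout, gave 113 to 174 such genes per interval. The SD of the differences between the 24 and 30 h arrays was 0.31, close to the 0.30 in the reference channel of the same 2 arrays. Of the 95 genes that stepped from 24 to 30 h, 29.5% were higher, against 56.3% with the sample channel alone, and without the dimmest 25% of genes 46 stepped.

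Over the whole course, the genes that rose most were near or below the reference until 30 h and far above it from 36 or 42 h on. The 10 largest rises comprised 3 ribosomal protein genes from 1 small region, SCO3427, SCO3429 and SCO3430 (3790678 to 3791717), for proteins L31, L28 and S14. Another 5 lay around a pair of non-ribosomal peptide synthase genes, SCO7682 and SCO7683, with SCO7677, SCO7686 and SCO7690 (8499392 to 8528107). The others were a metal transport gene, SCO2506 (2705052 to 2705822), and SCO4881 (5313363 to 5314301), for a polysaccharide biosynthesis-like protein. SCO3429 stood at 0.02, -0.66 and -0.65 at 18, 24 and 30 h and at 6.07 at 36 h and 7.53 at 60 h, a fitted log2 change of 9.76 ± 2.01 (SE, limma adjusted p = 0.0364). For SCO7683 the fitted change was 9.48 ± 1.77 (adjusted p = 0.0293) and for SCO4881, which stood at -0.42 at 36 h and 6.55 at 42 h, 9.66 ± 2.17 (adjusted p = 0.0454). A line fitted to such a step overstates it: the measured difference of SCO3429 between 60 and 18 h was 7.51. The SE of the line then holds its misfit to the step as well as scatter. The reference signal of SCO7683 was between 222 and 351, near the lowest on the arrays, so its fold depends on that dim signal. The same holds for SCO7677, SCO7682, SCO7686, SCO7690, SCO3430 and SCO4881, whose lowest reference signals lay between 193 and 251. That of SCO2506 was less dim, at 451 or above.

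Among the 10 largest falls, the neighbours ahpC (SCO5032) and ahpD (SCO5031, 5467332 to 5468429 together), for alkyl hydroperoxide reductase, each fell by 3.80 (SE 0.67 and 0.76, adjusted p = 0.0258 and 0.0356). SCO4761 (5172737 to 5173045), the co-chaperonin GroES, fell by 3.05 ± 0.54 (adjusted p = 0.0265). The glycolytic gene gap1 (SCO1947, 2080143 to 2081153) fell by 2.92 ± 0.47 and cydA (SCO3945, 4340932 to 4342437), a subunit of a cytochrome oxidase, by 2.70 ± 0.43. Another 3 were cypH (SCO7510), a peptidyl-prolyl isomerase, which fell by 2.56 ± 0.31, and the ribosomal stalk genes SCO4653 (L7/L12) and SCO4652 (L10), which fell by 2.59 ± 0.46 and 2.55 ± 0.47. The sugar transporter genes SCO7153 and SCO5578 fell by 2.96 ± 0.50 and 2.86 ± 0.50, but their values were nearly equal on every array, so the 2 features may read the same transcripts and their separate levels are uncertain.

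In all, 457 of 7729 genes had a linear trend (limma, adjusted over all genes), 384 rising and 73 falling, and 1721 had an unadjusted p under 0.05. All but 1 of the rising genes, 383, changed at least 2-fold. This count depended strongly on single arrays and on the fit. It was 812 without the 18 h array, 152 without 24 h, 131 without 30 h, 214 without 42 h and 79 without 48 h. It was 696 on a log2 scale of hours, 155 with the 24 and 30 h arrays averaged, and 1 with an intensity trend and a robust prior. With the sample channel alone it was 243, of which 70.8% rose, against 84% in the ratios. Within the 36 to 60 h arrays alone, and with the class of ratio as a batch term, 0 genes passed limma's test (1385 and 1611 at an unadjusted p under 0.05), while all 457 kept the sign of their slope in both of these fits. These genes were selected for their slope on the same arrays, so a kept sign is not a separate check.

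The 5 genes named among those past the spline test of any smooth change over time had the largest excess of the middle times over both ends. SCO0180 (168705 to 169556), a hypothetical protein, was at -1.39 at 18 h, 3.30 at 42 h and 0.05 at 60 h (limma adjusted p = 0.0380), and SCO6198 and SCO4801, also hypothetical, peaked at 2.88 at 30 h and 1.88 at 36 h. SCO5400 (5871855 to 5872811), a transport system kinase, peaked at 2.58 at 36 h, and bldKB (SCO5113, 5558498 to 5560300), the binding lipoprotein of an oligopeptide importer needed for development, at 2.05 at 30 h with -0.69 at 60 h (adjusted p = 0.0407). In total 468 genes passed the spline test, which a straight course can pass too (2320 at an unadjusted p under 0.05), of which 294 also had a linear trend and 174 did not. The count was 707 without the 18 h array, 244 without 60 h, 18 without 36 h, and 0 without 42 h or without 48 h (1743 and 1969 at an unadjusted p under 0.05).

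**Figure D2:**
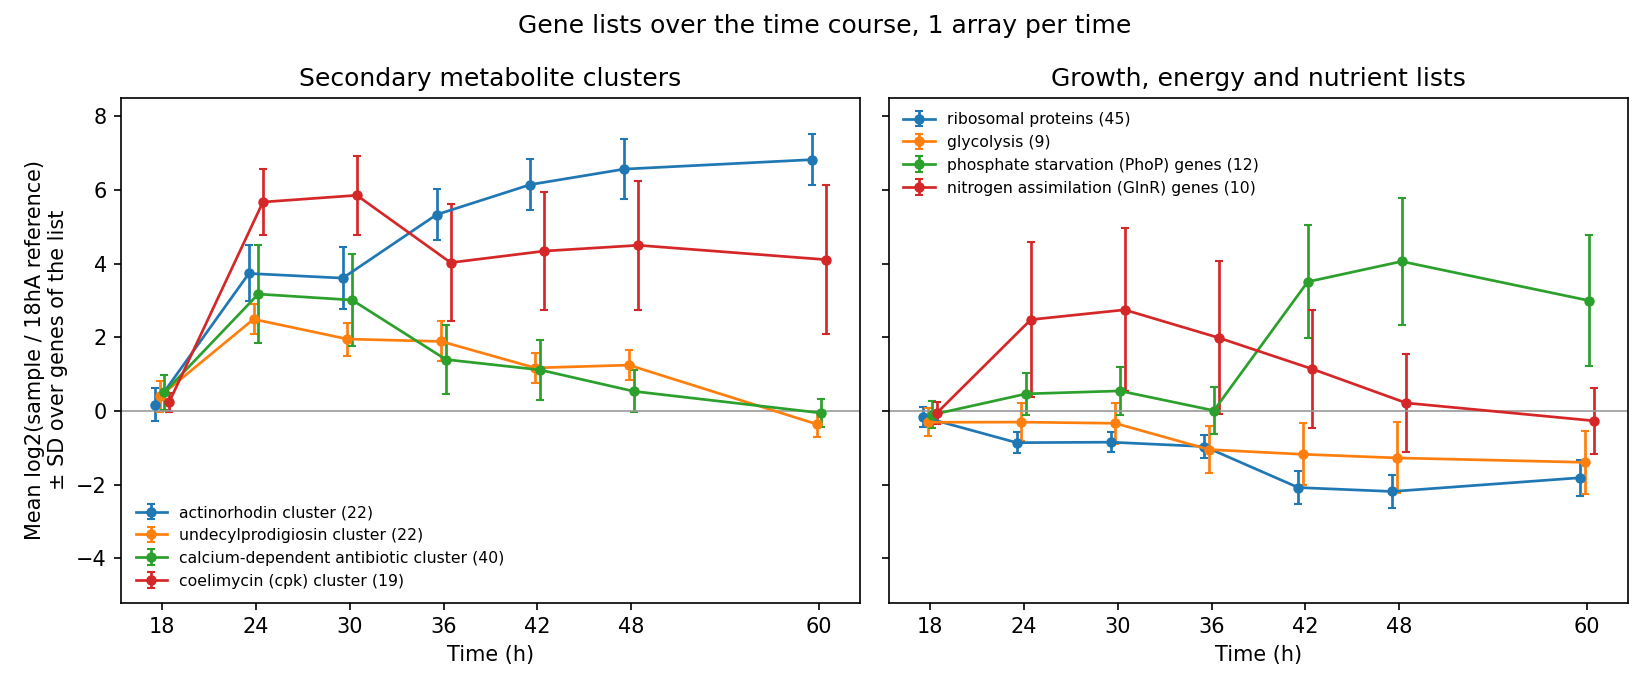
Points give the mean log2 ratio to the 18hA reference over the genes of a list against hours, with bars of ± SD over genes and the number of genes in the legend, 1 array per time. Actinorhodin genes climb to 6.83 at 60 h while the undecylprodigiosin and calcium-dependent antibiotic genes return to -0.36 and -0.05, and phosphate genes step up at 42 h, when the ribosomal protein genes step down.

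The 4 main antibiotic clusters followed different courses after their common increase. All 22 actinorhodin genes rose over the course (mean fitted change 6.10), from actVII (SCO5090, for a polyketide cyclase), 6.85 ± 1.25, to the activator gene actII-4 (SCO5085, 5528094 to 5528861), 4.49 ± 0.83, and the list reached 101-fold its 18 h level at 60 h. None of the 22 undecylprodigiosin genes passed the test singly, but as a list they fell against other genes (mean -1.44, adjusted p = 1.37e-05, but 0.556 with an estimated correlation between genes), from 4.27-fold at 24 h to 0.593 of the 18 h level at 60 h. The 40 genes of the calcium-dependent antibiotic, none past the test singly, likewise fell as a list (mean -2.07, adjusted p = 1.23e-09, but 0.545 with an estimated correlation), from 6.36-fold to 0.678. The 19 coelimycin genes had no trend as a list (mean 1.56) or singly and were still 14.6-fold above 18 h at 60 h, when they ranged from SCO6272 (FAD-binding protein, log2 ratio 0.86) to SCO6282 (3-oxoacyl-ACP reductase, 6.73). Adjusted p-values of the list test were 2.58e-16 for actinorhodin and 0.295 for coelimycin, and 0.545 and 0.888 with an estimated correlation. Without the 18 h array the coelimycin list fell (adjusted p = 0.000805), without 24 h it rose (0.0176), and without 60 h the undecylprodigiosin call was lost (0.545). Adjusted over the list alone, the counts of single genes were again 22, 0, 0 and 0. The mean of the actinorhodin list was ordered with time (Pearson r = 0.894, exact permutation p = 0.00575, adjusted 0.0479, rho = 0.964, p = 0.00278, and r = 0.954 without the 18 and 60 h arrays).

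Among the 18 antibiotic regulators, actII-4 and the regulator SCO5582 (2.92 ± 0.45, adjusted p = 0.02) rose, and the other 16 did not pass (2 adjusted over the list alone). The activator redD of the undecylprodigiosin cluster stood at 2.86 at 24 h, 3.10 at 36 h and 0.50 at 60 h, redZ at 1.35 and -0.02 at 24 and 60 h, and cdaR, of the calcium-dependent antibiotic cluster, at 1.45 at 30 h and -0.87 at 60 h (fitted change -2.15, adjusted p = 0.0910). In the coelimycin cluster SCO6280 and SCO6286 remained at 6.01 and 5.56 at 60 h, whereas SCO6288 went from 6.27 at 24 h to 2.98. The genes of the gamma-butyrolactone signal system, scbA and scbR, were highest at 24 h (4.05 and 2.73). Of the pleiotropic regulators, at 60 h afsR2 stood at 1.56, afsR at 0.39, adpA at -0.52, relA at 1.11, absA1 at -0.16, absA2 at -0.68, SCO4118 at 1.57 and SCO5231 at 0.07. As a list the regulators had no trend (adjusted p = 0.867), and the sign of the test turned with the sample channel alone (0.780).

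**Figure D3:**
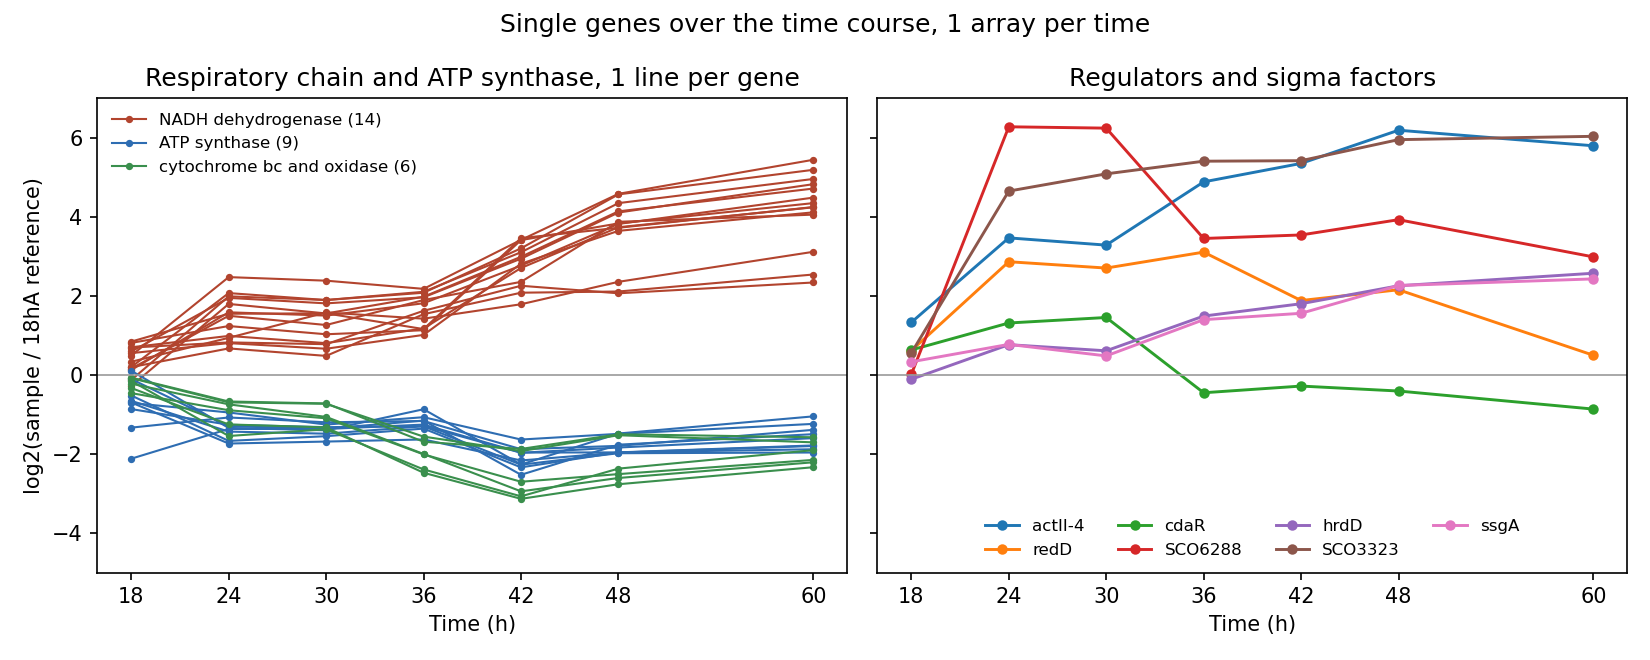
Lines join the log2 ratios of single genes to the 18hA reference against hours, 1 array per time, for the 14 NADH dehydrogenase, 9 ATP synthase and 6 cytochrome genes (left) and for 7 regulators and sigma factors (right). NADH dehydrogenase genes rise to between 2.34 and 5.44 at 60 h while those of the ATP synthase and cytochromes lie below 0, and SCO6288 is highest at 24 h while actII-4 and hrdD climb.

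The lists of ribosomal proteins, of transcription and translation factors and of glycolysis fell at the preset correlation between genes, but not with an estimated one (adjusted p = 0.545 for each), and the genes of 1 respiratory complex rose. Of 45 ribosomal protein genes 21 fell, none rose, and the lowest fitted changes were those of SCO4653 and SCO4652 above. SCO5591, for protein S16, was highest at -0.52. The mean was -1.88, and the list stood at 0.246 of its 18 h level at 48 h. Transcription and translation factors (mean -1.33) had 0 of 9 past the test, from SCO4661, elongation factor G (-2.33, adjusted p = 0.0524), to secE (-0.50), and fell as a list. In glycolysis 5 of 9 genes fell, gap1 (-2.92) together with the aldolase gene SCO3649, SCO1945, SCO1946 and SCO3096, of which the last 4 were chosen after their values were seen. Glucokinase, SCO2126, was highest at 0.27. The 14 genes of NADH dehydrogenase, the entry complex of the respiratory chain, SCO4562 to SCO4575, grouped after their values were seen, rose by 1.95 to 4.76, with SCO4572 highest (4.76 ± 0.56, adjusted p = 0.0113). The other 15 genes of that list, of the ATP synthase and the cytochrome bc complex and oxidase, did not pass, and qcrC (SCO2150) was lowest at -2.43 (adjusted p = 0.0751). This list therefore had a mean of 1.20, a median of -0.18 (both fitted changes) and no call (adjusted p = 0.0964), which became 0.0452 with the sample channel alone. The tricarboxylic acid cycle list had 1 of 11 genes past the test, SCO4855 of succinate dehydrogenase, which fell by 1.53 ± 0.32, and fumarate hydratase SCO5042 highest at 2.88 (adjusted p = 0.0896). List tests gave adjusted p = 7.09e-27 for ribosomal proteins, 1.94e-05 for both the factors and glycolysis, and 0.0560 for the cycle (0.545 with an estimated correlation). Adjusted over the list alone, 40 ribosomal, 6 factor and 6 glycolysis genes fell, 14 respiratory genes rose and 6 fell, and 1 gene of the cycle rose and 3 fell. The glycolysis mean was ordered with time (Pearson r = -0.920, exact permutation p = 4e-04, adjusted 0.00992, r = -0.934 without 18 and 60 h, and rho = -0.964, p = 0.00278, adjusted 0.0232). That of the respiratory chain was ordered by Pearson's r (0.896, exact permutation p = 0.00238, adjusted 0.0298, r = 0.745 without 18 and 60 h). By rho it did not pass after adjustment (0.857, p = 0.0238, adjusted 0.0744). Apart from glycolysis, the respiratory chain and the actinorhodin list above, no list passed with Pearson's r after adjustment over the 25 lists.

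The 10 nitrogen assimilation genes were on average 6.95-fold above 18 h at 30 h, with 9 at least 2-fold higher and 1 at least 2-fold lower. Their mean was 0.861 of the 18 h level at 60 h. Of them glnII (SCO2210), a glutamine synthetase, went from 4.81 at 30 h to -0.28, and urease subunit SCO1234 from 1.61 to -0.34. None passed singly, and the list fell (mean -1.65, adjusted p = 0.00407, 0.545 with an estimated correlation, 0.218 without the 60 h array). Of the 12 phosphate starvation genes, 11 were at least 2-fold higher at 42 h than at 36 h, and the list was 17.9-fold above 18 h at 48 h. The phosphate-binding protein gene pstS (SCO4142, 4556707 to 4557819) stood at -0.54 at 36 h and 6.17 at 42 h (fitted change 7.54, adjusted p = 0.0791), and the alkaline phosphatase gene SCO2068, 2.44 above 18 h already at 24 h, was lowest in fitted change (1.46). None passed over all genes, 9 rose adjusted over the list alone, and the list rose (mean 4.18, adjusted p = 2.12e-05, 0.545 with an estimated correlation). In nitrate reductases narJ3 (SCO4949) stood at 4.02 and narI2 (SCO0219) at -1.81 at 60 h, with no gene and no list trend (mean 0.51, median -0.08, adjusted p = 0.775), but a fall within the 36 to 60 h arrays (adjusted p = 0.0228). Siderophore genes, for iron uptake, rose as a list (mean 1.09, adjusted p = 0.00799, 0.556 with an estimated correlation, 0.125 without the 18 h array). Of 15 genes, 1 passed, the iron-siderophore transporter gene SCO0495 (1.69 ± 0.33, adjusted p = 0.0326), named after its value was seen, and 2 did adjusted over the list alone. Permease gene SCO0497 was highest (2.40) and monooxygenase gene SCO2783 lowest (-0.51).

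Development and stress lists were mixed. Of 14 developmental regulators, ssgA (SCO3926, 4319501 to 4319911), which guides cell division in sporulation, rose (2.30 ± 0.34, adjusted p = 0.0177), as did the regulator gene SCO1541 (2.71 ± 0.51, adjusted p = 0.0310). The other 12 did not pass, and 3 rose adjusted over the list alone. At 60 h the sigma factor SCO3323 stood at 6.03, SCO3579 at 3.59, SCO4768 at 3.38, whiH at 1.80, SCO4091 at 1.02, bldB at 0.31, SCO1950 at -0.01, and bldD, whiG, whiB and sigF between -0.46 and 0.13. Of 11 sigma factors hrdD (2.70 ± 0.34, adjusted p = 0.0113) and sig1 (2.36 ± 0.54, adjusted p = 0.0489) rose, 9 did not pass, and 6 rose and 1 fell adjusted over the list alone. The others stood at 60 h at 1.59 for hrdA, 1.91 for SCO5820, 0.17 for hrdC, -0.71 for sig8, 0.58 for sigE and 1.82 for rpoE. Terpene genes rose as a list (mean 1.20, adjusted p = 0.00015, but 0.545 with an estimated correlation) with 4 of 18 past the test (5 adjusted over the list alone), from the hypothetical protein SCO6761 (3.04 ± 0.55) to the lyase SCO5222 (-0.34, not past). Gas vesicle genes fell as a list (mean -1.74, adjusted p = 5.43e-05, but 0.545 with an estimated correlation), from gvpK (-0.98) to SCO6500 (-2.78), with 0 of 10 past the test and 2 adjusted over the list alone. Ectoine genes fell as a list (mean -1.76, adjusted p = 0.0280, but 0.545 with an estimated correlation), with SCO1865 at -1.31 and SCO1867 at -2.37 and none past singly. The adjusted p-values of the camera test were 0.289 for developmental regulators and 0.0533 for sigma factors, which had no call as lists by that test. Their means were ordered with time by Spearman's rho (0.964 and 0.929, exact permutation p adjusted 0.0232 and 0.0422). With Pearson's r they did not pass after adjustment (0.0729 and 0.0515).

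No list trend was called for 6 further lists. Aerial hyphae surface proteins (15 genes, mean 1.57, adjusted p = 0.0511) ranged at 60 h up to 6.92 for SCO6682, with SCO2716 at 0.31. The whiE spore pigment genes (8, mean 0.16, adjusted p = 0.954) had SCO5319 at -1.68 at 24 h and 0.15 at 60 h, and SCO5314 at 0.08 at 60 h. Fatty acid synthesis (7 genes, mean -0.46, adjusted p = 0.291) ranged in fitted change from SCO5535 at 0.37 to SCO2389 at -1.62. DNA replication (10 genes, adjusted p = 0.586) had a mean of 0.02, a median of 0.23 and a test pointing down, with SCO3878 at 0.81 and ftsW at -0.996. Heat shock genes (8, adjusted p = 0.0533) had a mean of -0.75, a median of 0.14 and a test pointing down. Of them GroES alone fell, 3 did adjusted over the list alone, and dnaJ was highest at 0.49. Stress genes (6, adjusted p = 0.295) had a mean of 0.27, a median of -0.31 and a test pointing down. The catalase gene katA stood at 0.57 at 30 h and 4.30 at 36 h, and SCO0596 was lowest at -2.03, while adjusted over the list alone 1 rose and 1 fell. In the aerial hyphae, whiE, fatty acid and DNA replication lists 0 genes passed, adjusted over all genes or over the list alone.

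Of the 25 lists, 4 rose and 8 fell with camera at the preset correlation, and 0 and 0 did with an estimated one. Within the 36 to 60 h arrays alone the calls of the actinorhodin (adjusted p = 3.14e-10), undecylprodigiosin (3.76e-21), calcium-dependent antibiotic (1.44e-27), ribosomal (4.38e-06), glycolysis (0.0433), nitrogen (1.04e-08) and terpene (0.000283) lists held, and the same 7 held with the class of ratio as a batch term. The batch fit takes most of its slope from the 36 to 60 h arrays too, so it is not a separate check. Both fits used the preset correlation, and the estimated one was not run for them. The phosphate (0.0778), ectoine (0.864) and translation factor (0.477) lists did not pass within those arrays, and the siderophore (0.183) and gas vesicle (0.864) lists turned in sign. Of the lists without a call over all arrays, the respiratory chain (0.000267) rose there, and the tricarboxylic acid (0.00457), nitrate reductase (0.0228), heat shock (0.0278) and fatty acid (0.0487) lists fell. The ectoine call was also lost with the sample channel alone (0.0786), after loess (0.0546) and without the 18 h array (0.681). Several lists lay near the threshold. After median centring the aerial hyphae (0.0398), sigma factor (0.0413) and respiratory chain (0.0481) lists also rose, and over all alternatives their adjusted p ranged from 0.0148 to 0.949, from 0.0217 to 0.545 and from 0.000267 to 0.821. Leaving out 1 array added the aerial hyphae list to those rising without 24 h (0.0261), 30 h (0.0163), 48 h (0.0489) or 60 h (0.0154). It added the sigma factors without 24 h (0.0239), 30 h (0.0434), 42 h (0.0497) or 48 h (0.0466), and the respiratory chain without 18 h (0.0381) or 48 h (0.0489). It added to those falling the tricarboxylic acid cycle without 24 h (0.0176), 30 h (0.0352), 42 h (0.0497) or 48 h (0.0338), heat shock without 18 h (0.000244), 42 h (0.0497) or 48 h (0.0489), and fatty acid synthesis without 18 h (0.000771).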

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

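Of the tests in this part, those of a single scale factor, of the processing classes and of another culture or preparation were chosen after the result was seen.

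The gfp feature, which is not a gene of the chromosome and entered no comparison, carried a signal in the later samples above that of the 18 h sample. Its ratio to the 18hA reference was 14.636 at 36 h, 16.1 at 42 h, 11.68 at 48 h and 10.626 at 60 h, after 0.978, 1.232 and 1.288 at 18, 24 and 30 h. Its sample intensity was 4524 at 36 h, 4103 at 42 h, 4052 at 48 h and 2175 at 60 h, against 255 at 18 h, with reference intensities between 205 and 622. The labels do not say whether the engineered strain carries a gfp gene, and no explanation of this signal was tested.

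The same boundary, from 30 to 36 h, holds the rise of genes at 3 loci: a metal transport operon (SCO2505 to SCO2507), a cluster of ribosomal protein paralogs (SCO3425 to SCO3430) and the non-ribosomal peptide cluster around SCO7683, together 26 genes that were all at least 2-fold higher at 36 h, by a median of 5.40 on the log2 scale. A single factor on the later arrays would move all genes alike, but their median moved by -0.04. A drop of the reference signal would need a fall as large as the rise. The sets' deposited reference signal, read on the same probes, moved by a median of -0.13 (-0.40 in 17 of the 26). The deposited sample intensity is this signal multiplied by the ratio, so it is not shown that this signal was the denominator of the ratio. A drop in the real denominator need not appear in it, and the test cannot exclude one. The rise was at least 4.22 in each of the 26. In 1783 genes matched to the sets in reference signal the median step was -0.02 (SD 0.66). That argues against a difference in processing or hybridisation tied to reference signal as the whole of the rise. Relief of zinc repression, since background knowledge puts these loci under a zinc-responsive repressor, stays open and without a test: those 17, whose values had not been looked at, rose by a median of 5.04, but lie beside genes picked for their rise and would move with them under other causes too. Another culture, RNA preparation or labelling of the later samples cannot be told apart from time, since the class of the ratio changes at this boundary, where 709 genes differ at least 2-fold (162 in the reference channel).

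The 24 and 30 h arrays were nearly alike, with a correlation across genes of 0.952 and an SD of differences of 0.31, close to the 0.30 in the reference channel. If both arrays had carried the same RNA, the differences of neighbouring genes would correlate no more in the sample channel than in the reference channel. The correlation between neighbouring genes was 0.202 in the sample channel and 0.055 in the reference channel, a difference of 0.15 (95% interval 0.093 to 0.21, 1000 bootstraps over blocks of 50 genes), which argues against the same RNA on both. The deposited sample intensity of these arrays is the reference intensity multiplied by the ratio, so the channels are not independent readings. The undecylprodigiosin list was lower in all 22 genes at 30 h (mean -0.54) and the siderophore list higher in all 15 (0.60). No biological explanation was tested, and a small real change between these times remains open.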

How the results depend on the processing

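The fits with the 24 and 30 h arrays averaged, with the 36 to 60 h arrays alone, with the class of ratio as a batch term, with loess and without the common scale factor of the later ratios were chosen after the data were seen. Of 214 recomputed counts 158 stayed within 1.5 times their value and 56 did not. For the 34 named genes past the threshold, 266 of 680 refits no longer passed and none reversed. Of the 34, 18 still passed with the sample channel alone, 15 without 42 h, 8 without 24 h or without 30 h, 7 with these averaged, 6 without 48 h, and 0 with a robust prior, the batch term or within 36 to 60 h. For the named genes not past it, 36 of 1696 refits passed. For the 12 lists with a call, 188 of 216 refits kept it, 25 lost it and 3 reversed, and for the 13 without, 191 of 234 stayed so, 40 gained one and 3 reversed. Leaving out 1 array at a time moved the linear trend from 79 to 812 genes (74 to 477 rising, 5 to 335 falling), the spline test from 0 to 707 genes, and the lists from 4 to 7 rising and from 6 to 10 falling. Other fits gave 243 trend genes (172 rising) with the sample channel alone, 1 (1 rising, 0 falling) with an intensity trend and a robust prior, 696 (157 falling) on log2 hours, 155 (146 rising, 9 falling) with 24 and 30 h averaged, and 0 (0 rising, 0 falling) both within 36 to 60 h and with the batch term. The last 2 keep 2 and 3 residual degrees of freedom, and the slopes of all 457 genes kept their sign in every fit (445 of 445 tested without the dimmest 25%). Selection for a slope on the same arrays favours a kept sign. Without the dimmest 25% of genes, the step from 24 to 30 h held 46 genes. At a threshold of 1.5-fold 3429, 3379, 3717, 4035, 3616 and 3163 genes differed from 18 h at 24 to 60 h, and at 4-fold 506, 478, 614, 855, 771 and 665. Rising lists numbered 7 after median centring and 7 with 24 and 30 h averaged, and with an estimated correlation 0 rose and 0 fell. Counted where the list passed in at least 1 of the compared fits, the sign of the list test reversed for coelimycin without 18 h (adjusted p = 0.000805, up to 0.35 without another array and there not reversed), for siderophores within 36 to 60 h (0.183) and with the batch term (0.705), for gas vesicles within 36 to 60 h (0.864), and for nitrate reductases in those 2 fits (0.0228 and 0.0217). For moved and reversed results the cause was not tested. Background correction and the summary over probes could not be varied on gene-level values and were not run. Dim reference signals limit the folds of the largest rises. No paired analysis was possible because every time has a single array.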

Other observations

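The runs of neighbouring genes in this part were searched for after the data were seen, with at least 5 genes in a row moving at least 4-fold between neighbouring arrays, while the tests of the reference signal and of the order of arrays were chosen before.

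Outside the fixed lists, several further clusters moved together between 18 and 24 h, without a replicate. Carotenoid genes (SCO0185 to SCO0193, 173768 to 184797), for phytoene and lycopene enzymes, were higher by a median of 2.95 on the log2 scale at 24 h, and 8 of these 9 were lower again at 36 h by a median of -3.17. A run of 22 genes for glycosyl transferases and sugar nucleotide enzymes (SCO0381 to SCO0402, 395939 to 424406) was higher by 3.56 and stood at a median log2 ratio of 4.42 at 60 h. Genes for breakdown of aromatic acids were higher, phenylacetate genes SCO7469 to SCO7475 by 3.61 and protocatechuate genes SCO6699 to SCO6703 by 2.38, of which the former stood at 3.53 and the latter at 0.21 at 60 h. Sulfate assimilation genes (SCO6094 to SCO6102, 6693977 to 6702585) were lower by a median of -3.31 at 24 h, at a log2 ratio of -4.28, and passed through -2.54 at 36 h and -0.92 at 48 h to 0 at 60 h. The run around cysteine synthase (SCO2910 to SCO2914) was lower by a median of -2.78 at 24 h and stood at -0.34 at 60 h.

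Later steps were narrower. A sugar transport run (SCO1897 to SCO1901, 2031485 to 2036536) was high on the 36 h array alone, 3.52 above 30 h and then -3.32 from there to 42 h. A run with ABC transporter and solute-binding lipoprotein genes (SCO0471 to SCO0478, 491901 to 499807) was higher by 3.95 at 36 h and stood at 3.48 at 60 h. Runs of 5 or more such genes numbered 14 higher and 2 lower from 18 to 24 h, 5 and 2 from 30 to 36 h, 2 and 1 from 36 to 42 h, and 0 in the other intervals.

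Between 36 and 42 h the phosphate genes went up and all 45 ribosomal protein genes went down, by a median of -0.95. A drop of the reference signal would need a fall as large as the rise of the phosphate list. The deposited reference signal of that list moved by a median of -0.23. This signal is not shown to be the denominator of the deposited ratio, so the test cannot exclude such a drop. Depletion of phosphate in the medium stays open and without a test. The 9 neighbours of SCO4881 (SCO4873 to SCO4882) rose by a median of 3.99, but that gene was picked for its step at 42 h and genes beside it would move with it under other causes too. The reference signal of these 9 moved by a median of -0.54. Its steps ranged from 0.04 in SCO4879 to -1.63 in SCO4878, whose ratio rose by 2.28. Phosphate in the medium is not given in the sources used here, and the fall of the ribosomal genes was not tested for an origin.

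Chance order of the arrays was tested by refitting the linear and the spline model with 100 orders of the 7 arrays, the real one included and mirror images left out. For the linear trend 1 of 100 orders, the real one, gave 457 genes, and the highest of the others gave 2. For the spline test 1 of 100, again the real one, gave 468 genes, and the highest other gave 281, from an order that moves only the 24 h array to the end. No other order drawn gave as many calls, which argues against a chance order for both counts. The orders drawn were a part of all 5040, and a swap of only the nearly alike 24 and 30 h arrays was not among them. Other orders do not test a technical difference that follows time.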
